A study of Drosophila melanogaster with 2 samples.

How the data were processed

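ChIP-seq of GFP-tagged CG4707 was measured in 2 biological replicates of whole embryos. Chromatin was sonicated to 200 to 800 bp, per the labels. Regions were called by the authors on each replicate and on the pooled reads, against the same control alignment, per the deposited file listing. A list of 3470 peaks that passed an irreproducible discovery rate threshold was deposited beside them. It equals the 3470 pooled regions of highest signal, as checked in the lists. The aligner and the peak caller are not given in the sources used here, and the build is dm6 per the labels. The deposited peak signal is a score in the caller's own unit, which the authors did not describe, so only its ranks were compared between lists. The deposited lists also give the −log10 of the q-value per region by the authors' caller, which was the same for all 3470 peaks and was used only for that check. Other deposited columns give the distance of the summit from the start of the region. Depth is unknown, because only region lists were used, and every interval covers counting error only.

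Summits were placed on the Ensembl release 115 annotation of the same assembly, with sequence from the Release 6 genome. No region passed the end of a chromosome. A summit within 500 bp of any annotated TSS was called a promoter summit, and other summits were placed, in this order, in 5' UTR, 3' UTR, coding exon, non-coding exon, intron or intergenic sequence. The background was 26075 pooled regions below the threshold that overlap no peak. Regions were set against it with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Intervals of shares are exact Clopper-Pearson 95% intervals. For the agreement of replicates, lists were called overlapping at 1 bp or more and rotated 1000 times along their chromosomes.

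The gene lists, the known motifs, the alternative settings and the tests of the comparisons were fixed before the data were examined, with the exceptions given here. The count of head-to-head genes once per peak, protein-coding genes as the background of the lists, the tests of signal and summit position at ribosomal protein genes, and the promoter share of unshared replicate regions were added later. So were the tests of hypotheses about ribosomal protein genes and about peaks without the 8-mer. The X comparison was first computed over protein-coding genes by mistake. It was changed to annotated TSSs, as fixed beforehand, after that first value had been seen. The cytochrome P450 list was narrowed after its count had been seen, because its name pattern also took 2 cyclophilin genes. The list as first written, with 85 members, gave an adjusted p of 0.0403 by Fisher's exact test in place of 0.0387. The list patterns for nos and h matched no gene, since the annotation names them nanos and hry, so these genes were left out of their lists. Genes of each list were counted as bound when a TSS lay within 500 bp of a peak summit and set against all other genes. The lists cover ribosome, translation, respiration, proteasome, chaperonin, splicing, small RNA, patterning, maternal, cell cycle, insulator, chemosensory, cuticle, protease and P450 genes.

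Motifs were sought on both strands within 100 bp of the summit, in peaks and in sub-threshold regions matched 1:1 on promoter class and GC decile. The 8-mer search ran on 2L, 2R and X, and its 10 best were tested again on 3L, 3R and 4. Spearman correlations with signal were tested with 100000 permutations. Named genes are those within 500 bp of the 20 peaks of highest signal (at most 3 per peak, or the gene the peak lies in or nearest to), up to 4 bound members of each list with the highest signal, and CG4707 and w. Other genes named were chosen after their values were seen. These are the unbound ribosomal protein genes and those that share a peak with a member of another list.

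Alternatives were a stricter threshold (the higher-signal part of the peaks), each replicate alone, promoter windows of 250 and 1000 bp, the most upstream TSS, other backgrounds, a 50 bp sequence window, flanking windows, 6-mers and other overlap rules. In simulated lists over 18164 genes, 100 of 100 enriched lists and 2 of 400 unenriched lists were called. These lists were of equal size and drawn at random, with peaks planted at a large share of the enriched members. The rates do not carry over to weaker enrichment, depletion, other list sizes or clustered genes that share a peak. In simulated regions, an 8-mer planted in 8% of 3470 regions was ranked first, and 0 were called without it. Simulated replicates that share 60% of 3470 regions overlapped at 61.1%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.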

Results

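CG4707 is a Drosophila melanogaster gene, and the data locate its protein on the genome. Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole embryos of a transgenic line that expresses CG4707 fused at its C terminus to GFP. Embryos of both sexes were collected at 0 to 14 h. The series holds 1 group with 2 biological replicates, numbered 2 and 3 in the labels, and no second condition. A free-text field of the labels calls both libraries an input control, while their title, assay and antibody fields describe a transcription factor ChIP-seq experiment with a separate control. They were read as immunoprecipitated libraries, and that reading rests on the labels. Only region lists were used here, so the sequencing depth is unknown. Each replicate and the pooled data gave 30000 regions, and 3470 peaks passed the authors' reproducibility threshold. Regions had a median width of 380 bp in the pooled list. The peak signal is the value of the authors' own caller, and is used here only to describe, rank, filter or compare regions within a list. All coordinates are on dm6.

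The first comparison asks how far the 2 replicates recovered the same regions. Of the 3470 regions of highest signal in replicate 2, 2626 (75.7%, exact 95% interval 74.2 to 77.1) overlapped the 3470 of highest signal in replicate 3. When 1 list was rotated along its chromosomes 1000 times, the overlap averaged 1.66% and reached at most 2.71% (permutation test by rotation, p = 0.001, the smallest the rotations can give). The strongest peaks were shared most often. Peaks were split into 4 equal groups by pooled signal. In the highest group, 97.9% stood among the top 3470 of both replicates, against 95.4%, 70.7% and 20.2% in the following groups. Over 3336 peaks with a summit of each replicate within 100 bp, the signals had a Spearman correlation of 0.71. This correlation is across peaks, which are not independent replicates. The pooled list contains the reads of both replicates, so these groups are not independent of the replicate lists. The lowest group also lies next to the cut at rank 3470, where small shifts in rank take a peak out of the top. Those 3336 peaks were 96.1% of all peaks. Of the top regions, 1.33% in replicate 2 and 1.18% in replicate 3 overlapped none of the 30000 regions of the other replicate.

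**Figure D1:**
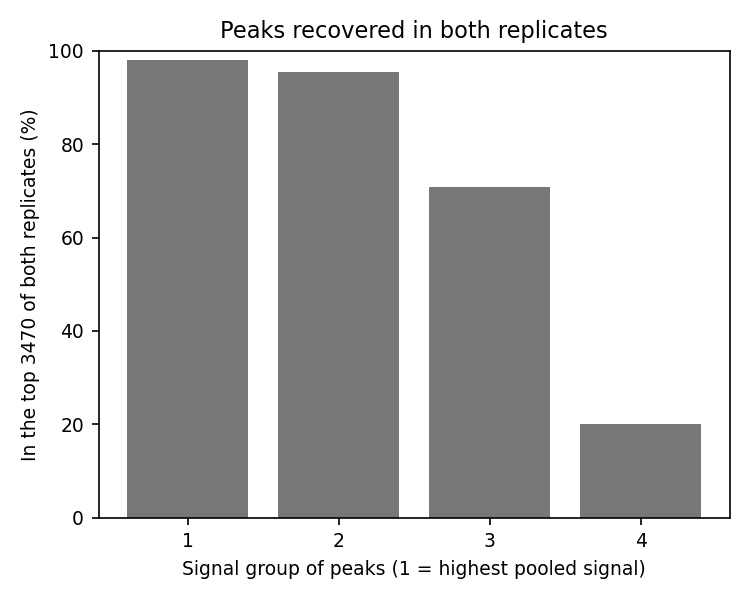
Bars show, for each of 4 equal groups of the 3470 peaks by pooled signal (x axis, 1 = highest), the percent of peaks that lie among the 3470 highest-signal regions of both replicates (y axis). The share falls from 97.9% in the highest group to 20.2% in the lowest, which lies next to the cut at rank 3470.

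The second comparison asks where on genes the tagged protein lay. Summits within 500 bp of an annotated transcription start site (TSS) made up 1569 of 3470 peaks (45.2%, interval 43.6 to 46.9). Among 26075 sub-threshold regions, which came from the same libraries and caller and overlap no peak, the share was 26.5% (odds ratio 2.29, two-sided Fisher's exact test, p = 1.95e-108). Random positions on the same chromosomes gave 13.6%. Pooled regions just below the threshold, at ranks 3471 to 6000, were at promoters in 43.0% of cases. The difference from the sub-threshold regions thus rests mostly on weaker regions. Introns held 38.1% of peaks and 44.9% of sub-threshold regions (Fisher's exact test, adjusted p = 3.05e-14), and intergenic sequence 13.4% and 21.2% (adjusted p = 2.77e-28). Coding exons held 0.461% and 2.95% (Fisher's exact test, adjusted p = 3.31e-24). The shares were 1.12% and 2.25% in 3' UTRs (Fisher's exact test, adjusted p = 5.69e-06) and 0.634% and 1.17% in 5' UTRs (adjusted p = 0.00377). Non-coding exons held 1.07% and 1.05% (adjusted p = 0.93, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the classes). Promoters were assigned first, so a higher promoter share lowers the other shares, and these tests are not separate results. Outside promoters, introns held 1321 of 1901 peaks and 11712 of 19176 sub-threshold regions, a larger share of the peaks, which was not tested. Random positions gave 39.4% in introns, 27.2% in intergenic sequence and 13.1% in coding exons. The median position of promoter summits was -73 bp from the TSS and 69.5% lay upstream, against -15 bp and 55.0% in sub-threshold promoter regions.

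Peaks occurred on all arms, at 28.5 per Mb on 2L, 25.3 on 2R, 26.4 on 3L, 24.8 on 3R, 25.7 on X and 14.1 on 4. Of 3953 annotated TSSs on X, 9.31% lay within 500 bp of a peak summit, against 10.1% of 19860 on the major autosome arms (odds ratio 0.911, two-sided Fisher's exact test, p = 0.117). Without replicate 3 the same exact test gave p = 0.0116, so the call depended on the replicate. A gene can have several annotated TSSs, and 1 peak can count for several of them. The TSSs are thus not independent, and both p-values of this exact test may be too small. Genes with a head-to-head neighbour were more frequent among bound genes. Of 1675 bound protein-coding genes 42.9% had an opposite-strand protein-coding TSS within 500 bp upstream, against 25.2% of 12270 unbound ones (odds ratio 2.23, two-sided Fisher's exact test, p = 1.29e-48). A peak between such genes counts for both of them in that test. Counted once per peak and against sub-threshold promoter regions, the shares were 30.4% and 25.8% (odds ratio 1.26, Fisher's exact test, p = 0.00049), a smaller difference, by a test chosen after the first result was seen.

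The highest peak (signal 4736) lay on chromosome 2R from 17265023 to 17265595, with its summit 175 bp upstream of a TSS of mbl, which encodes the splicing regulator Muscleblind. The next (signal 3971) lay on 3R from 16235466 to 16236133 in an intron of tara. The next after it (signal 3743) lay on X from 21054082 to 21054583, upstream of bves and Stt3A, which encodes an oligosaccharyltransferase subunit. The peak of rank 4 (signal 3220) was intergenic, on 2L from 12002823 to 12003283 and 802 bp from the nearest TSS, that of Hacd1. Of the 20 highest peaks, 14 were at promoters. The remaining promoter peaks were at ClpX, Tollo, sm, CG42327, Rtnl1, CG14100, CG32176 with Coq4, CG8034, CG11151, px, RecQ4 and Vinc. Intronic peaks lay in Trl and psq, which encode GAGA-binding proteins, and in CG31635 and chn.

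The gene list comparison asks which of 25 gene groups had promoters near a peak. In all, 1902 of 18164 genes (10.5%) had a TSS within 500 bp of a summit. Genes of cytosolic ribosomal proteins stood furthest above this, with 67 of 93 bound (72.0%, interval 61.8 to 80.9, odds ratio 22.8, Fisher's exact test, adjusted p = 9.7e-44). RpS27 (signal 868), RpS4 (794), RpL31 (661) and RpL14 (626) had the highest peaks of the group. Their summits lay within 17 bp of a TSS. The 26 unbound members included RpL10Aa, RpL22-like, RpL24-like, RpS19b, RpS28a and RpS5b. The group was bound in each replicate alone, at 70 of 93 in replicate 2 and 65 of 93 in replicate 3. Genes of translation factors were bound in 13 of 52 cases (25%, odds ratio 2.86, Fisher's exact test, adjusted p = 0.00924), led by eIF4EHP (signal 812), eIF6 (542) and eEF1gamma (532). Genes of insulator and architectural proteins were bound in 10 of 29 cases (34.5%, odds ratio 4.52, Fisher's exact test, adjusted p = 0.00238), led by Chro (1029), Dref (573) and Cp190 (516). The Dref peak is also that of RpL13, with its summit at 5 bp from the TSS of RpL13 and -89 bp from that of Dref. Among the translation factors, eIF1 was counted through the peak of RpL28, with its summit at -347 bp from the TSS of eIF1. All adjusted p-values of the lists are from two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 25 lists. With only genes near a pooled region as the background, translation factors and insulator genes both lost their call (Fisher's exact test, adjusted p = 0.0886 each). The insulator list also lost it under the stricter threshold (Fisher's exact test, adjusted p = 0.17).

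Peaks at ribosomal protein genes also differed from other promoter peaks in strength and position, by tests chosen after their binding was seen. The median signal was 328 over 70 such peaks and 183 over 1499 other promoter peaks, a log2 difference of 0.84 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The median summit lay at -2.5 bp from the TSS, against -81 bp (two-sided permutation test, p = 0.00033). Within 50 bp of a TSS lay 92.9% of the summits, against 23.5%.

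Chemosensory receptor genes were bound less often than other genes, with 0 of 179 (Fisher's exact test, adjusted p = 5.06e-08), as were cuticle protein genes with 1 of 117 (adjusted p = 0.000348), the 1 being Cpr65Av. Cytochrome P450 genes were bound in 2 of 83 cases, Cyp6u1 and Cyp317a1 (Fisher's exact test, adjusted p = 0.0387). Replication-dependent histone genes were bound in 0 of 111 cases (Fisher's exact test, adjusted p = 5.77e-05). None of these histone genes lay near any of the 30000 pooled regions, and they stand in near-identical repeated copies, where reads may not be placed. With genes near a pooled region as the background, the receptor, cuticle and P450 lists lost their call (Fisher's exact test, adjusted p = 0.319, 0.458 and 0.616). Only 10 receptor, 13 cuticle and 17 P450 genes lay near a pooled region, too few to show that the difference is gone. The P450 call was also lost with the stricter threshold (adjusted p = 0.176), a 250 bp window (0.163) and the most upstream TSS (0.101), all by Fisher's exact test.

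The other 18 lists did not pass the test. Among housekeeping groups, 12 of 73 mitochondrial ribosomal protein genes were bound (Fisher's exact test, adjusted p = 0.202), with mRpS23 (signal 1400) and mRpS10 (1173) highest. They were called more often under the stricter threshold (10 bound, Fisher's exact test, adjusted p = 0.0248). The counts were 1 of 48 for proteasome subunits, 4 of 84 for oxidative phosphorylation, 2 of 33 for aminoacyl-tRNA synthetases, 0 of 8 for the CCT chaperonin, 1 of 15 for mitochondrial import and 3 of 37 for the spliceosome. Proteasome genes were called less often with a 1000 bp window (1 bound, Fisher's exact test, adjusted p = 0.0399). Heat shock genes were bound in 6 of 26 cases (Fisher's exact test, adjusted p = 0.134), with Hsp83 (951) and Hsp27 (510) highest. That list was called without replicate 2 (7 bound, Fisher's exact test, adjusted p = 0.0377), without replicate 3 (9 bound, adjusted p = 0.00598), and with windows of 250 bp (adjusted p = 0.0445) and 1000 bp (adjusted p = 0.0399). Among developmental genes, the counts were 0 of 8 for Hox genes, 2 of 21 for segmentation genes, 3 of 14 for dorsal-ventral genes, 4 of 12 for the Enhancer of split complex (Fisher's exact test, adjusted p = 0.0932), 4 of 16 for germ plasm and maternal effect genes and 4 of 27 for cell cycle genes. The Enhancer of split list was called more often at 1000 bp (5 bound, Fisher's exact test, adjusted p = 0.0399). For small RNA genes they were 22 of 290 tRNA, 4 of 32 snRNA and 19 of 269 snoRNA genes. The tRNA list was called less often under the stricter threshold (5 bound, Fisher's exact test, adjusted p = 0.00982), without replicate 2 (14 bound, adjusted p = 0.00602) and with genes near a pooled region as the background (adjusted p = 0.017). The snoRNA list was called less often without replicate 2 (16 bound, Fisher's exact test, adjusted p = 0.0377) and at 250 bp (10 bound, adjusted p = 0.03), but more often at 1000 bp (58 bound, adjusted p = 0.00104), the opposite direction. Several of the 19 were counted through the peak of a ribosomal protein gene, such as snoRNA:U49:66Da through that of RpL14 (summit at -469 bp). So were tRNA:Phe-GAA-1-2 (peak of RpL17) and, among maternal effect genes, plu (peak of RpS18). Whether a wider window adds such neighbours was not tested. Jonah protease genes were bound in 0 of 16 cases.

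**Figure D2:**
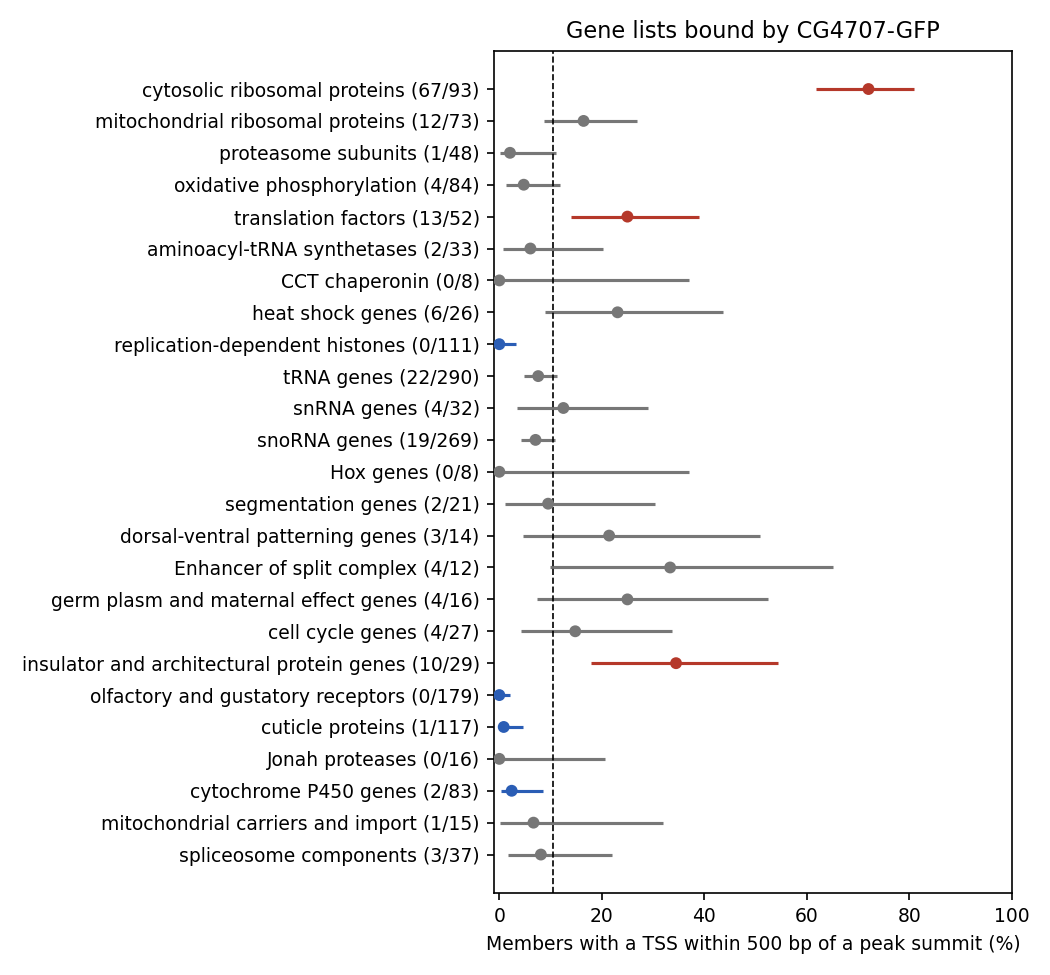
Points show the percent of each gene list's members with a TSS within 500 bp of a peak summit (x axis), with exact 95% intervals as lines, and the bound and total members beside each name (y axis). Red lists were bound more often and blue lists less often than other genes at an adjusted p under 0.05, grey lists did not pass, and the dashed line marks the 10.5% of all genes. Cytosolic ribosomal proteins stand apart at 72.0%.

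The sequence comparison asks which motifs lay within 100 bp of the summits. Of 13 known motifs, 2 were more frequent in peaks than in sub-threshold regions matched on promoter class and GC content. The GAGA motif occurred in 7.35% of peaks and 5.19% of matched regions (odds ratio 1.45, Fisher's exact test, adjusted p = 0.00163). The CTCF core occurred in 3.40% and 1.96% (odds ratio 1.76, adjusted p = 0.00163, two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 13 motifs). GAGA lost its call within 50 bp of the summit (Fisher's exact test, adjusted p = 0.84) and CTCF under the stricter threshold and without replicate 3 (adjusted p = 0.606 and 0.466). The motifs DRE, Motif 1, Motif 5 E-box, Motif 6, Motif 7, TATA box, Initiator, Zelda, Su(Hw), Pho and Grainyhead did not pass.

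An open search of 32853 8-mers on 2L, 2R and X found 18 more frequent in peaks and 0 less frequent at an adjusted p under 0.05. The best was CACTGTGC, on the other strand GCACAGTG. On the chromosomes kept out of the search (3L, 3R and 4), it occurred in 124 of 1556 peaks (7.97%, interval 6.67 to 9.43) and in 33 of 1584 matched regions (2.08%, odds ratio 4.07, two-sided Fisher's exact test, p = 9.34e-15). Of the 10 best 8-mers, 9 passed there, and AGTGGGCC did not (Fisher's exact test, adjusted p = 0.0685, Benjamini-Hochberg over 10). These 8-mers overlap or are variants of each other, so the 9 are not independent results. Which 8-mer was best depended on the setting, though the best ones named here all hold ACAGTG on one of the strands. The best 6-mer was ACAGTG. ACAGTGGG was best under the stricter threshold and within 50 bp of the summit, and CACAGTGG against flanking windows. In the main setting ACAGTGGG occurred in 8.42% of the held-out peaks and 1.39% of matched regions (odds ratio 6.53, Fisher's exact test, adjusted p = 1.29e-20), a larger odds ratio than that of CACTGTGC. The base before CACTGTGC was C at 87.3% of 236 sites. Over all peaks, 344 of 3470 (9.91%) held the 8-mer, at promoters (8.86%) as elsewhere (10.8%), against 1.99% of sub-threshold regions. These shares include 2L, 2R and X, on which the 8-mer was chosen, and so may be too far apart. Sites gathered at the summit, with a median distance of 62 bp over 597 sites within 300 bp. Of 5401 sites in the genome, 7.15% lay within 100 bp of a peak summit. The share was 16.8% at promoters, 7.49% in introns, 3.97% in intergenic sequence and 0.524% in coding exons. Peaks with or without the 8-mer were dense at promoters (45.2%, against 13.6% of random positions). They were rare in coding exons (0.461%, against 13.1%). The shares of sites thus do not show a preference for sites at promoters.

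**Figure D3:**
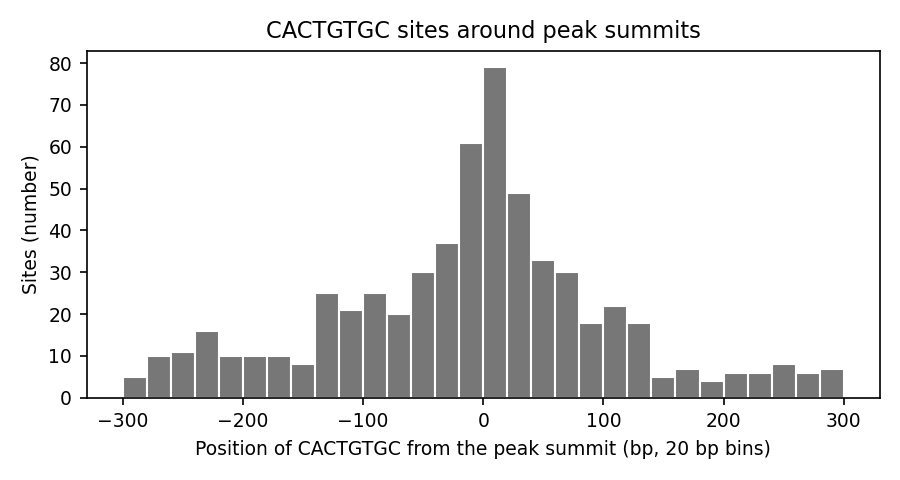
Bars count CACTGTGC sites (y axis) by their distance from the peak summit in 20 bp bins (x axis), over 597 sites within 300 bp. The highest bin, of 79 sites, begins at the summit.

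Strong peaks held the 8-mer more often. In the 4 signal groups, from the highest, it occurred in 18.4%, 9.34%, 7.37% and 4.50% of peaks (Spearman's rho 0.18 across peaks, permutation test, p = 1e-05, the smallest possible). In the 100 highest regions it occurred in 41 (interval 31.3 to 51.3), and in 10 of the 20 highest peaks, though not at mbl or tara. The promoter share was 50.3%, 42.9%, 43.0% and 44.6% in these groups (rho 0.042, permutation test, p = 0.013). By rank it was 63% in the 100 highest regions, 58% in the next 150, 48% at ranks 251 to 500, 45% at ranks 501 to 1000 and 41.8% at ranks 1001 to 2000. The fall did not go on to the threshold, with 44.6% at ranks 2001 to 3470. Just below it, at ranks 3471 to 6000, the promoter share was 43.0%. Further down it was 37.15% at ranks 6001 to 10000 and 18.2% at ranks 25001 to 30000. With the mean rank in both replicates in place of pooled signal, the promoter relation was not called (rho 0.025, p = 0.137).

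**Figure D4:**
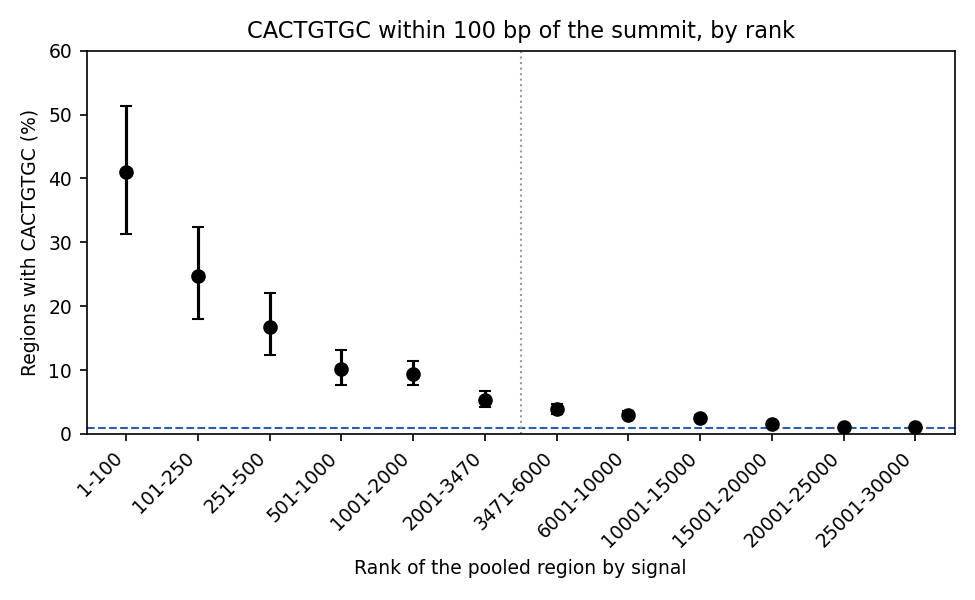
Points show the percent of pooled regions with CACTGTGC within 100 bp of the summit (y axis) by rank of signal (x axis), with exact 95% intervals as bars. The dotted line marks the peak threshold at rank 3470 and the dashed line the 0.919% found in random windows, and the share falls from 41% in the highest 100 regions to 1.14% in the lowest 5000.

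The CG4707 gene itself lies on 2R from 24604595 to 24607023, on the minus strand. A peak (signal 454, rank 350, region 24607090 to 24607291) lay with its summit at -149 bp from the gene's start and held the 8-mer. The 20 kb on either side of the gene's midpoint held 15 pooled regions, at percentile 77.1 of equal windows around 13945 protein-coding genes. The gene w, a common transgene marker, had no pooled region.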

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

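Counting head-to-head genes once per peak (30.4%), protein-coding genes as the background of the lists and the P450 list as first written were chosen after seeing the data. Of the tested values that answer a comparison, 43 kept their direction and their side of the threshold under an alternative, and 4 that were called under neither setting changed direction. These were the X share under the stricter threshold (5.36%) and the non-coding exon share under the stricter threshold (0.980%), against the lowest-signal part of the background (1.07%) and without replicate 2 (1.01%, against 1.24% without replicate 3, which kept the direction). A further 25 counts stayed within 1.5 times the main count, which is a looser rule: lists bound less often ranged from 3 to 6 among these (main count 4), lists bound more often from 3 to 4 (3) and 8-mers or 6-mers that passed from 8 to 10 (9). The 5' UTR share under the stricter threshold was 0.692% (Fisher's exact test, adjusted p = 0.0919), with fewer peaks tested. The X share of bound TSSs ranged from 9.23% to 9.41% with 1 replicate left out, and only without replicate 3 did it pass the test. The number of lists bound more often went from 3 to 6 with a window of 1000 bp, to 1 with genes near a pooled region as the background and to 8 with circular rotations. The number bound less often went from 4 to 1 with genes near a pooled region (tRNA genes, Fisher's exact test, adjusted p = 0.017) and to 0 with rotations. Rotated peaks lay near 2.94% of all genes on average, against the 10.5% bound, so rotations set a list against random placement and not against other genes, and their calls are not evidence that a list differs from other genes. The histone list has no member near a pooled region and gave no value with that background. The ribosomal protein list was called under every setting tried for the lists, with a highest adjusted p of 0.00999, by rotations. The number of motifs more frequent in peaks went from 2 to 1 under the stricter threshold, 1 within 50 bp of the summit, 4 against the lowest-signal part of the background and 8 against flanking windows. With 1 replicate left out it ranged from 1 to 2, and motifs less frequent in peaks from 0 to 1. The rho of signal with promoter class was 0.025 with the mean rank of both replicates. Among single lists and motifs, 21 results passed the threshold only under an alternative in the main direction, 16 lost it and 42 changed direction, none of them called in the main setting. Of the 42, 6 were called under the alternative: snoRNA genes at 1000 bp (58 bound), tRNA genes by rotations (22), Motif 7 against the lowest-signal part of the background (9.65%), and Motif 7 (9.57%), DRE (2.25%) and Su(Hw) (1.90%) against flanking windows. The other 36 were called in neither setting. By rotations they were 19 snoRNA, 4 oxidative phosphorylation, 3 spliceosome, 2 synthetase, 2 segmentation and 1 mitochondrial import genes. Near a pooled region they were 19 snoRNA and 4 cell cycle genes, at 250 bp 3 spliceosome and 2 segmentation genes, at 1000 bp 4 snRNA genes, and at the most upstream TSS 2 segmentation genes. Under the stricter threshold they were 1 gene each of the cell cycle, snRNA and import lists, Motif 1 (1.38%), Motif 5 and Motif 6 (7.61% each), Motif 7 (8.82%) and Su(Hw) (2.02%). Within 50 bp they were Grainyhead (0.317%), Motif 1 (0.548%), Motif 7 (4.64%) and Su(Hw) (1.18%), and against the other backgrounds DRE (2.30%, lowest-signal part) and Zelda (1.04%, flanking windows). With either replicate left out they were Motif 7 (9.51% to 9.77%) and Su(Hw) (2.05% to 2.07%). Only without replicate 2 it was DRE (2.51%, with the direction kept at 2.33% without replicate 3). Only without replicate 3 they were 5 synthetase genes, 2 snRNA genes, Grainyhead (0.893%), Motif 1 (1.53%) and Zelda (0.749%), with the direction kept without replicate 2 (2 and 6 genes, 0.548%, 1.47% and 0.922%). The cause of these changes was not tested. No paired analysis was possible because there is 1 group. Depth is unknown and its effect was not tested.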

Other observations

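The comparison over all housekeeping lists, the test of weak peaks on chromosomes kept out of the search, the comparison of weak peaks with ranks 3471 to 6000, the wider initiator window, the promoter share of unshared replicate regions, and the tests of signal and summit position at ribosomal protein genes were chosen after the result was seen. Below the threshold the 8-mer was still found more often than in random windows, except in the lowest ranks. It occurred in 3.83% of pooled regions at ranks 3471 to 6000 (interval 3.12 to 4.66), 3.02% at ranks 6001 to 10000 and 1.14% at ranks 25001 to 30000 (interval 0.865 to 1.47), which includes the 0.919% of 34700 random windows. The replicates differed in their unshared regions, by a test over regions with a single library on each side. It does not measure variation between libraries. Of the top regions of replicate 2 outside the top of replicate 3, 54.7% were at promoters, against 39.7% the other way round (odds ratio 1.84, two-sided Fisher's exact test, p = 5e-10). On chromosome 4, replicate 2 had 169 regions and replicate 3 had 292, and of their 3470 highest 18 and 17, a difference that was not tested.

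Ribosomal protein genes were bound most often of the 25 lists, but their peaks rarely held the 8-mer: 1 of 70 (1.43%, interval 0.0362 to 7.70), against 1.61% of sub-threshold promoter regions (two-sided Fisher's exact test, p = 1) and 9.21% of other promoter peaks (p = 0.0172). That housekeeping groups in general were bound at this rate is argued against by the 9 other housekeeping lists, translation factors and heat shock genes included, whose shares ran from 0% to 25% with a highest upper bound of 43.6% (heat shock genes), below the lower bound of 61.8% for ribosomal protein genes. A bias towards the most open or most transcribed promoters stays open, because transcription was not measured and ribosomal protein genes may be transcribed more than those groups. The 8-mer lay within 500 bp of a TSS in 8.60% of ribosomal protein genes and 5.73% of other protein-coding genes (Fisher's exact test, p = 0.257), too few to tell whether it has a part. No biological explanation was tested by the design, which has 1 group.

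A hypothesis is that a polypyrimidine initiator (YCTTTY), known from ribosomal protein genes, goes with these peaks. Protein-coding genes outside the ribosomal list with its C within 2 bp of a TSS were bound in 23 of 104 cases (22.1%), against 11.5% of the others (odds ratio 2.18, two-sided Fisher's exact test, p = 0.0019). That window found the initiator in only 16 of 93 ribosomal protein genes, since it lies mostly a few bp downstream of their annotated TSSs, and within the ribosomal list 12 of these 16 were bound against 55 of 77 without it (odds ratio 1.2, Fisher's exact test, p = 1). A window reaching 10 bp downstream, set after those positions were seen, gave 61 of 312 bound (19.6%) against 11.4% (odds ratio 1.88, Fisher's exact test, p = 3.48e-05), and 59 of 75 against 8 of 18 within the ribosomal list (p = 0.00711). Genes with the initiator may also be more active, so sequence and activity cannot be separated by these tests.

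Most peaks lacked the 8-mer, which 9.91% held, and whether weak peaks are background stays open. In the lowest of 4 signal groups 4.50% held it, against 1.73% of matched sub-threshold regions (two-sided Fisher's exact test, p = 0.00126), but the 8-mer was chosen partly on these peaks and the controls include far weaker regions. On 3L, 3R and 4 alone the shares were 3.80% (15 of 395) and 1.77% (7 of 395, Fisher's exact test, p = 0.128), and ranks 3471 to 6000 there held it at 3.32% (Fisher's exact test, p = 0.633). The 8-mer does not take in every enriched form of the sequence. CCACTGTA, with A in place of the G after CACTGT, occurred in 4.69% of peaks on 3L, 3R and 4. It occurred in 0.821% of matched regions there (odds ratio 5.95, Fisher's exact test, adjusted p = 1.64e-11). Whether those peaks also held CACTGTGC was not counted. The 6-mer ACAGTG occurred in 24.1% of peaks on these chromosomes and 11.5% of matched regions (Fisher's exact test, p = 1.6e-20). Those peaks include ones with CACTGTGC. How many peaks without the 8-mer a looser sequence accounts for cannot be told apart from other recruitment. A weight matrix built on 2L, 2R and X separated held-out peaks without the 8-mer from matched regions with an area under the curve of 0.562 (95% bootstrap interval 0.541 to 0.583), between the bounds of 0.55 and 0.6 set beforehand. A cut-off at the 95th percentile of matched regions was passed by 7.89% of 1432 such peaks. Of 1551 matched regions without the 8-mer, 3.03% passed it.

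A transgene may add copies of its own locus to a library and raise the number of regions called there. The window around CG4707 was at percentile 77.1, with 15 pooled regions against 23 at the 95th percentile of windows, which argues against a large excess. The margin is narrow for a count of 15, and a control from the same line would carry the same copies and hide them. The peak upstream of CG4707 held the 8-mer, and binding of the protein to its own promoter was not tested further.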
